A study of Mus musculus with 18 samples.

How the data were processed

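The data come from HTGTS, a translocation sequencing assay based on linear amplification, which reads the junctions that one chosen chromosomal break, the bait, forms with other broken DNA ends, the preys. Here the bait was the 5′ part of Sμ, the switch region in front of the IgM constant gene, in splenic B cells of mice whose immunoglobulin heavy (IgH) and kappa loci were already assembled. Class switch recombination joins a break in Sμ to a break in a switch region further downstream, so preys in Sγ1 and Sε mark joins between switch regions and preys in Sμ mark joins inside it. Per the labels' protocols, the cells were depleted of CD43-positive cells, grown for 4 days with an antibody to CD40 and interleukin 4, a treatment that directs switching to Sγ1 and Sε, and their genomic DNA was amplified from a biotinylated primer in Sμ, with a nested PCR and an AflII digest that removes the unrearranged product.

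The 18 libraries fall into 5 groups by their labels: wild type (3 libraries), a second control group (4), DNA-PKcs 5A (5), Xrcc4-null (2) and DNA-PKcs-null (4). In the 5A mice the phosphorylation sites of the T2609 cluster of DNA-PKcs, the kinase that holds DNA ends for nonhomologous end joining, are changed. The labels carry a further genotype, which sets the second control group apart and varies within the 5A group. It is not reported here, and neither are the comparison of the 2 control groups and the alternative that rest on it. XRCC4 is a partner of DNA ligase IV, which seals ends in the same pathway. A summary sheet among the authors' deposited files gives 1 animal for 2 of the 3 wild-type libraries, and these were taken to be libraries 2 and 3, by elimination from the sheet names. A chi-square test of their counts over 5 prey classes, which takes junctions as independent, found that they differed by more than counting error (p = 0.000123). Only 25 of their 922 and 888 distinct junctions in the switch regions were identical, so their junction lists are not copies of each other. That does not exclude that both sampled 1 pool of DNA. By the same chi-square test, libraries 1 and 2 differed less (p = 0.0148) and libraries 1 and 3 more (p = 7.21e-08). The test therefore does not check which libraries share an animal. The mean of libraries 2 and 3 was used as 1 replicate, which gives 17 animals and 6 control animals. The plan written before the data were examined treated every library as a replicate, and that version was kept as an alternative.

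Per the labels' protocols, the authors aligned reads to mm9sr, which is mm9 with the C57BL/6 sequence of chromosome 12 from 114494415 to 114666816 replaced by the 129 sequence of the same region. Per the submitters' processing notes, Bowtie2 and mm9 were used, with no version given. The junction caller, its filters and the handling of repeat copies are not given in the sources used here. The authors deposited 1 sheet per library of whole-number junction counts by region and orientation and by microhomology class, with each count as a fraction of its total, lists of single junctions, and sheets of substituted bait bases, which were not used for the measures. A junction list gives the prey position and strand, and where bait and prey lie in the read. Lists pooled over a genotype were not used, since they keep no animals apart. In 154 lines of the lists the values were empty, and 20768 junctions remained. The number of junctions in the lists was compared with the authors' counts in 144 pairs of library and class. It was equal in 119, and in 0 pairs did it differ by more than the empty lines. In DNA-PKcs-null replicate 2 the sheet's total of 1141 holds 300 junctions more than its fractions allow, all outside IgH, so the total of 841 that the fractions give was used.

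Coordinates are those of mm9sr as the files give them. Inside and beyond the replaced segment of chromosome 12 they do not equal mm9 positions. They were used unconverted, except that listed junctions upstream of Sμ and in the first 20 kb past it were also placed in mm9 by their sequence. The listed junctions span 114661503 to 114671498 for Sμ, 114558735 to 114587936 for Sγ1 and 114507352 to 114516998 for Sε, and 94.8% of reads began at position 114669257, the bait. IgH is transcribed toward lower coordinates. The first 60 bait bases were also found in mm9 itself, on chromosome 12 from 114664850 to 114664909, between the J segments and Ighm by the GENCODE annotation. Of 1314 preys outside IgH, 97.1% matched mm9 at their listed position in at least 90% of bases.

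From each library 34 measures were computed. Regional shares are percent of all junctions in Sμ, Sγ1, Sε, other IgH and outside IgH, and Sγ1 plus Sε as percent of the 3 switch regions. The structure of a junction comes from the overlap of bait and prey in the read. Shared bases are microhomology, which can be assigned to either end, 0 is a blunt join, and a gap between bait and prey is an insertion. Microhomology of 4 or more bases is called long. Shares by structure rest on the authors' counts by class, and mean lengths and the profile of lengths on the lists, so they were computed only where a library's lists were used, which sets a smaller n. For Sε of 5A replicate 2 these were lists by structure class without blunt joins. Its lengths came from them, with blunt joins added from the counts, but its Sε positions were not used. A prey joined as a deletion on the same chromosome has the strand of a productive switch, and the other strand is inversional. The remaining measures are the median distance of deletional preys from the upstream end of their region (kb), the median bait length (bases), substitutions per 1000 bait bases against the commonest base at each position, with 21 primer bases and at least 2 bases beside the junction left out, and the chromosome 12 share of junctions outside IgH.

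The comparisons were 5A, DNA-PKcs-null and Xrcc4-null each against the animals of both control groups together (the controls), and 5A against each null. Each value was tested by a two-sided exact permutation test of the difference between means over animals, using all assignments of animals to groups, with the smaller tail doubled. Adjusted p-values are Benjamini-Hochberg values over the 34 measures of a comparison, with a threshold of 0.05. The smallest p the design can give is 0.00433 for 5A against controls, 0.00952 for DNA-PKcs-null against controls, 0.0159 for 5A against DNA-PKcs-null, 0.0714 for Xrcc4-null against controls and 0.0952 for 5A against Xrcc4-null, all by exact permutation. On simulated counts with no difference between groups, the procedure gave an unadjusted exact p at or under 0.05 in 5.08% of measures for 5A against controls and called 0%. With the odds of 10 of 25 measures changed by a factor of 2, it called 93.2% of the changed and 1.87% of the unchanged measures, and for DNA-PKcs-null against controls 91.1% and 1.93%, over 100 simulations each. In the simulations the measures varied independently, and both groups had the spread of the controls. The real measures depend on each other, and some spread more widely in 5A. The simulated rates therefore do not give the rate of false calls in these data.

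Depth ran from 263 junctions (5A replicate 4) to 4936 (Xrcc4-null replicate 1). Wilson intervals at 95% are given for shares of single libraries, and these, like the limit that a count of 0 allows (3 counts), cover counting error only, since reads without molecular identifiers can repeat a molecule. Read names place the libraries in 5 sequencing runs. Run 1 holds all wild-type libraries, second-control 2 to 4, 5A 1, 3, 4 and 5, Xrcc4-null 2 and DNA-PKcs-null 4. Run 2 holds 5A 2 and DNA-PKcs-null 2, and the other libraries lie in runs 3 to 5, with 1 group in each.

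Features were named by a rule set before the data were examined: the 3 switch regions, each structure class, and outside IgH the 10 one-megabase windows with junctions in most libraries. Gene names inside those windows come from the GENCODE M1 annotation of mm9, outside that rule, and were chosen after the values were seen. The alternatives planned beforehand were pooling of junctions over a group, a log-odds scale, 1 junction per position, other denominators, other lengths for long microhomology, single regions, both orientations, single runs, either control group alone, the replicate number as a block, and leaving out each library. They were run on 25 of the 34 measures in all 5 comparisons. Which of these differences are described in detail was chosen after the values were seen, as were the averaging of the 2 wild-type libraries, the IgH segments outside the switch regions and the contrast of Sε with Sγ1. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, and samtools 1.23.1 for reference sequence.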

Results

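HTGTS junctions from an Sμ bait were collected from activated splenic B cells in 18 libraries, taken as 17 animals. The groups were wild type (2 animals, 3 libraries), a second control group (4), DNA-PKcs 5A (5), DNA-PKcs-null (4) and Xrcc4-null (2). The wild-type libraries held 805, 1010 and 1038 junctions and those of the second control group 3192, 1317, 615 and 1022. The 5A libraries held 602, 2157, 711, 263 and 812 junctions, the DNA-PKcs-null libraries 2523, 841, 2984 and 1182, and the Xrcc4-null libraries 4936 and 1198. Values are means over animals ± SD, and the animals of both control groups together are the controls (n = 6). The labels do not say whether the other libraries came from separate animals, so p-values measure the spread between libraries taken as 1 animal each.

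In control cells most junctions lay in the 2 downstream switch regions that this stimulation activates. Sε, in front of the IgE constant gene, took 43.6% ± 4.89 of all junctions (SD, n = 6), Sγ1, in front of the IgG1 constant gene, 21.5% ± 4.75, and Sμ itself 25.5% ± 2.31. Other IgH positions held 2.87% ± 0.570 and the rest of the genome 6.50% ± 1.20. Of the Sγ1 and Sε junctions, 25.3% ± 2.27 were blunt, 55.3% ± 2.65 had microhomology and 19.4% ± 2.53 carried an insertion. Inversional joins made up 7.20% ± 1.19 of them.

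In cells with the 5A form of DNA-PKcs, a larger share of junctions lay in Sμ and a smaller share in Sε, while the share in Sγ1 did not change measurably. Shares alone cannot tell a rise in Sμ joins from a fall in Sε joins. Sμ held 43.9% ± 8.21 of junctions (SD, n = 5) against 25.5% in controls, and Sε 20.4% ± 12.6 against 43.6%. Sγ1 held 21.5% ± 2.55 against 21.5% ± 4.75. This depends on the denominator, since as percent of junctions outside Sμ the Sγ1 share was higher in 5A by 10.3 percentage points (exact permutation p = 0.0390, adjusted 0.0697). Of all junctions in the 3 switch regions, Sγ1 and Sε together took 48.5% ± 11.1 in 5A cells and 71.9% ± 2.62 in controls. Other IgH positions rose to 6.18% ± 3.73.

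The exact permutation test gave an adjusted p of 0.0184 for Sμ and for the combined share of Sγ1 and Sε, with no overlap between the 5 animals and the 6 controls, 0.0294 for Sε, 0.0421 for other IgH positions and 0.961 for Sγ1. Across the 34 measures of this comparison 16 passed, 11 higher and 5 lower in 5A. The 5A animals were spread widely in Sε. Replicate 2, the deepest library, had 39.3% (Wilson 95% interval 37.2 to 41.3), inside the control range of 36.4% to 50.7%, and replicate 4, the shallowest, 7.60% (4.98 to 11.5). Among libraries of sequencing run 1 alone (4 animals against 5), Sμ differed by 21.1 percentage points, Sε by -27.2, other IgH positions by 4.26, and the combined Sγ1 and Sε share by -26.9. Each had an exact p of 0.0159, the smallest that split allows, and an adjusted p of 0.0540.

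The Sε call ended without 5A replicate 3 (difference -24.7 percentage points, adjusted exact p = 0.0589), replicate 4 (-20.0, 0.0540) or replicate 5 (-22.2, 0.0540). The call for other IgH positions held only without wild-type replicate 2 or 3 or 5A replicate 2, and ended in the other 9 fits that left out 1 library. Without 5A replicate 4 that difference dropped from 3.31 to 1.72 percentage points. The share outside IgH (8.04% ± 0.878 against 6.50% ± 1.20, n = 5 and 6) had an adjusted exact p of 0.0775, which became 0.0268 without wild-type replicate 3.

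**Figure D1:**
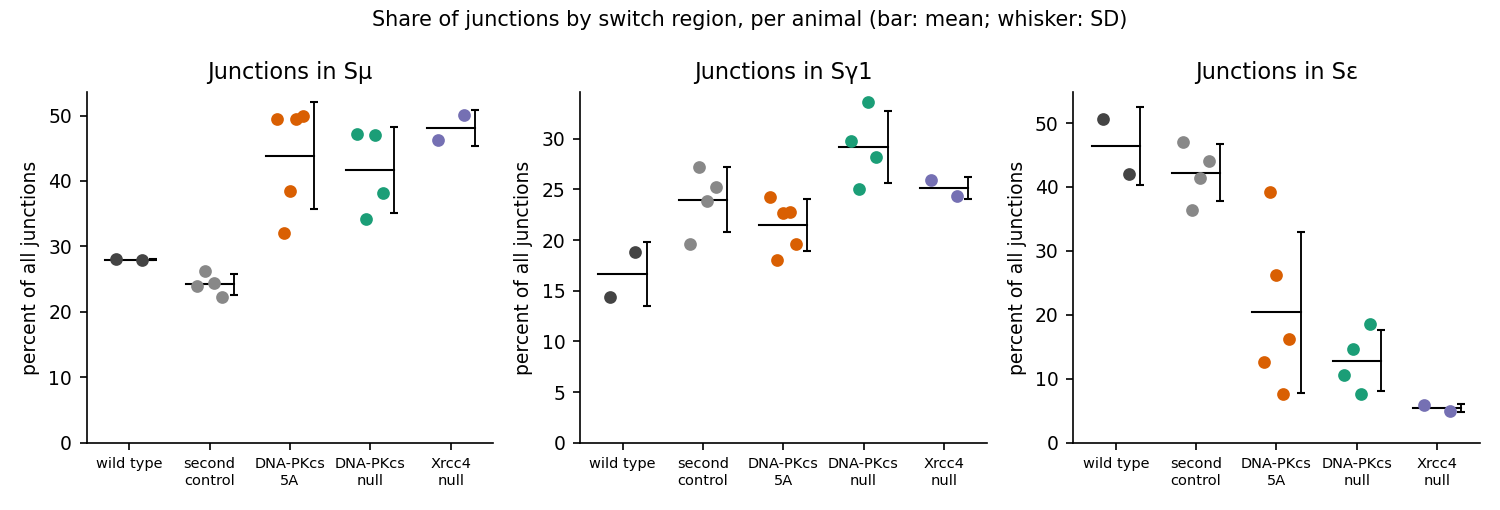
Percent of all junctions in Sμ, Sγ1 and Sε (y axis) for each animal (points) of the 5 groups (x axis), with the mean (bar) and SD (whisker). Sε falls from 43.6% in the pooled controls to 20.4% in DNA-PKcs 5A, 12.8% in DNA-PKcs-null and 5.47% in Xrcc4-null animals, while 1 of the 5A animals, at 39.3%, lies among the controls.

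The 5A junctions also used more and longer microhomology, mainly in Sμ and Sγ1. Junctions with 4 or more shared bases made up 19.3% ± 1.95 of Sγ1 joins in 5A (n = 5) and 8.21% ± 1.09 in controls (n = 6), a ratio of 2.36. Blunt joins fell to 13.3% ± 2.81 from 25.9% ± 3.57 in Sμ and to 16.4% ± 3.60 from 24.04% ± 3.00 in Sγ1. In Sε, blunt joins were 31.0% ± 9.06 against 25.9% ± 2.15 and long microhomology was 8.73% ± 1.62 against 6.15% ± 1.62, and neither difference passed the test.

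By exact permutation the adjusted p was 0.0184 for long microhomology in Sγ1 and for blunt joins in Sμ and in Sγ1, with every 5A animal beyond every control, and 0.336 and 0.0606 for blunt joins and long microhomology in Sε. In Sγ1 and Sε together, long microhomology was 14.6% ± 2.80 against 6.86% ± 1.23 (n = 5 and 6, adjusted exact p = 0.0184), blunt joins 22.7% ± 4.03 against 25.3% ± 2.27 (0.282), any microhomology 63.5% ± 4.74 against 55.3% ± 2.65 (0.0294) and insertions 13.9% ± 3.66 against 19.4% ± 2.53 (0.0368). The insertion difference was -6.76 percentage points against the second control group alone and -2.98 against wild type alone (exact p = 0.286). The mean microhomology of joins without insertion was 1.94 ± 0.225 bases (n = 4) against 1.46 ± 0.0993 (n = 5, adjusted exact p = 0.0415). All these values over Sγ1 and Sε together also carry the mix of the regions. Sε, with less long microhomology than Sγ1, gave on average a smaller part of these joins in 5A than in controls. In Sμ, long microhomology was 17.1% ± 2.58 against 10.5% ± 4.04 (n = 5 and 6, adjusted exact p = 0.0460).

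Within run 1 the differences were 8.55 percentage points for long microhomology in Sγ1 and Sε together, 11.5 in Sγ1, -12.8 for blunt joins in Sμ and -7.52 in Sγ1, each with an exact p of 0.0159 and an adjusted p of 0.0540. For any microhomology the run 1 difference was 9.13, for insertions -5.89 and for long microhomology in Sμ 6.87 percentage points, and for the mean length 0.544 bases. The call for any microhomology ended without 5A replicate 2 (difference 9.35, adjusted exact p = 0.0540), replicate 4 (7.15) or replicate 5 (7.61). For insertions the call ended in 10 of 12 such fits and for the mean length in 8 of 10, all but those without wild-type replicate 2 or 3, and for long microhomology in Sμ in 9 of 12, all but those and the fit without second-control replicate 3. The highest adjusted exact p over those fits was 0.0694 for insertions, 0.0863 for the mean length and 0.101 for long microhomology in Sμ. The difference in blunt joins of Sγ1 and Sε together, -2.65 percentage points, ran from -3.60 without 5A replicate 2 to -1.49 without 5A replicate 1. In Sε, the blunt-join difference of 5.12 percentage points dropped to 1.62 without 5A replicate 4 (adjusted exact p = 0.615) and passed, at 7.93, without 5A replicate 1 (0.0498), and long microhomology passed without second-control replicate 4 (3.00) or 5A replicate 1 (3.12).

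**Figure D2:**
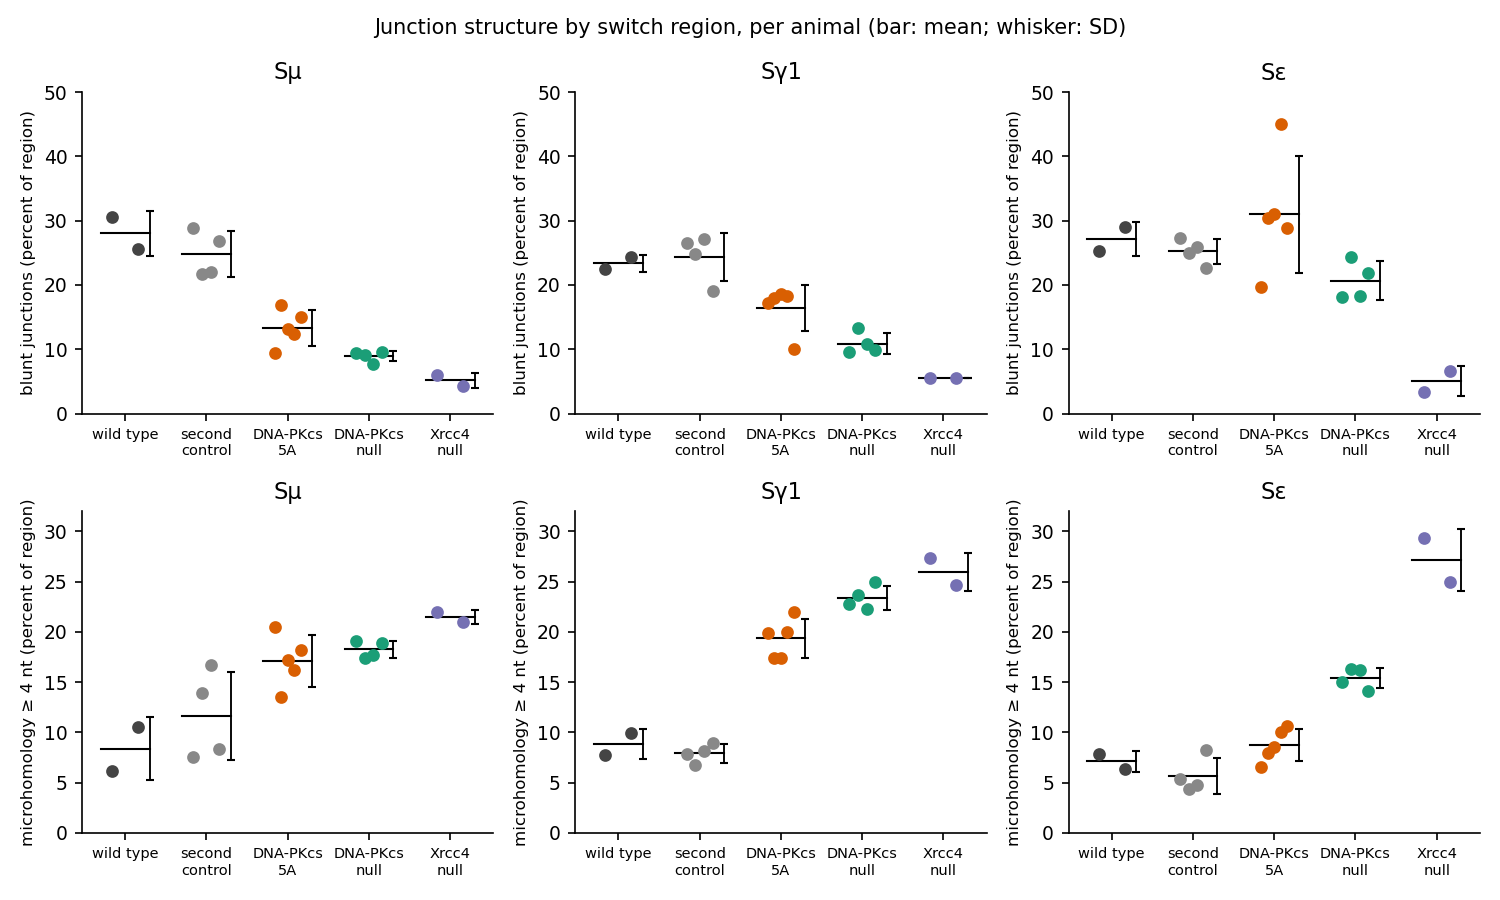
Blunt joins (top) and joins with 4 or more bases of microhomology (bottom) as percent of the junctions of Sμ, Sγ1 and Sε (y axes), with 1 point per animal, the mean (bar) and the SD (whisker) for each group (x axis). In Sε the 5A mean for blunt joins, 31.0%, lies above the control mean of 25.9%, whereas in Sγ1 it lies below it, 16.4% against 24.04%.

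Inversional joins were less frequent in Sε of 5A cells. They made up 2.15% ± 1.43 of Sε junctions in 5A (n = 5) and 5.10% ± 1.39 in controls (n = 6). The animals did not overlap, but only narrowly, with the highest 5A animal at 3.788% and the lowest control at 3.803%. The 5A libraries held 2, 23, 3, 0 and 5 inversional Sε joins, so the separation rests on few junctions. In Sγ1 inversional joins made up 11.8% ± 5.73 against 11.8% ± 1.84. There the 5A animals spread from 6.67% to 18.5% and controls from 8.84% to 14.0%. The difference between the regions was not tested. The exact p was 0.00433 for Sε, or 0.00866 adjusted over both regions. Replicate 4 had 0 inversional joins among 20 Sε junctions, where the Wilson interval reaches 16.1%. Over both regions the share was 7.71% ± 4.15 against 7.20% ± 1.19 (adjusted exact p = 0.845), with a run 1 difference of 1.20 percentage points. The split by region was an alternative to this pooled value. In Sμ it was 30.4% ± 3.83 against 24.1% ± 5.88 (n = 5 and 6, adjusted exact p = 0.114).

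The median positions of junctions inside the switch regions did not differ detectably between 5A and controls, but more 5A junctions lay far downstream in Sμ. The median distance from the upstream end of the region was 3.22 ± 0.0971 kb in Sμ (n = 4) against 3.21 ± 0.225 kb (n = 6, adjusted exact p = 0.911). It was 18.9 ± 0.298 kb against 17.8 ± 2.22 kb in Sγ1 and 2.79 ± 0.221 kb against 2.68 ± 0.0981 kb in Sε. In an alternative measure, the share of junctions beyond the 90th percentile of control distances, 5A had 15.7% ± 3.01 in Sμ against 10.2% ± 2.07 (n = 4 and 6, adjusted exact p = 0.0270). It had 13.8% ± 1.92 against 10.1% ± 1.07 in Sε (n = 4 and 5, 0.0360 by exact permutation) and 20.5% ± 3.12 against 11.5% ± 5.96 in Sγ1 (n = 4 and 6, 0.0648). Control shares lie near the set 10% by construction. The Sμ call ended without 5A replicate 1 (difference 4.05), 2 (6.04), 3 (5.67) or 4 (6.28), the Sε call in 9 of 10 fits, all but that without wild-type replicate 3 (highest adjusted exact p 0.0762), and Sγ1 passed without second-control replicate 3 (10.6). Bait length, bait substitutions (1.57 ± 0.515 against 2.27 ± 0.640 per 1000 bases) and the chromosome 12 share of junctions outside IgH (20.99% ± 9.27 against 12.9% ± 5.47) also missed the threshold.

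Cells without DNA-PKcs also had smaller shares of Sε junctions and of blunt joins. Sε held 12.8% ± 4.74 of junctions (n = 4) against 43.6% ± 4.89 in controls (n = 6), Sγ1 rose to 29.2% ± 3.55 from 21.5% ± 4.75, and Sμ to 41.6% ± 6.56 from 25.5% ± 2.31. Of the Sγ1 and Sε junctions 14.0% ± 2.58 were blunt against 25.3% ± 2.27, and 20.9% ± 0.208 had long microhomology against 6.86% ± 1.23, a ratio of 3.04. These pooled values also carry the mix of the regions, as Sε was a smaller part of these joins than in controls. Within single regions, long microhomology was higher by 15.2 percentage points in Sγ1 and 9.26 in Sε (adjusted exact p = 0.0162 for each). Blunt joins were lower in each region, at 8.94% ± 0.812 in Sμ, 10.9% ± 1.67 in Sγ1 and 20.7% ± 3.04 in Sε. Inversional joins rose to 11.2% ± 0.873 from 7.20% ± 1.19 in Sγ1 and Sε together and to 37.1% ± 2.43 from 24.1% ± 5.88 in Sμ.

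Of the 34 measures 27 passed, 18 higher and 9 lower. The adjusted exact p was 0.0162 for the shares of Sμ and Sε, for blunt joins, long microhomology and inversional joins in Sγ1 and Sε together, and for inversional joins in Sμ. It was 0.0374 for the Sγ1 share and 0.0282 for blunt joins in Sε. Taken alone, neither Sγ1 (13.0% ± 1.64 against 11.8% ± 1.84 inversional, exact p = 0.305) nor Sε (6.89% ± 2.73 against 5.10% ± 1.39, exact p = 0.200) differed detectably in orientation, and a larger part of the pooled joins came from Sγ1, where inversions are commoner. Run 1 holds 1 animal of this group, which differed from the controls of that run by -24.4 percentage points in Sε share, 12.4 in Sμ share, 6.25 in Sγ1 share, -10.3 in blunt joins, 13.6 in long microhomology and 4.40 in inversional joins (smallest possible exact p = 0.333).

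The Sγ1 call ended without wild-type replicate 1 (difference 6.20 percentage points), second-control replicate 1 (7.25) or 3 (8.10), or DNA-PKcs-null replicate 1 (7.42), 3 (6.15) or 4 (7.96). The Sε call for blunt joins ended without DNA-PKcs-null replicate 1 (-4.30), 3 (-4.40) or 4 (-5.59). Against the second control group alone the Sγ1 difference was 5.18 (adjusted exact p = 0.104) and the Sε difference in blunt joins -4.55 (0.0777), and against wild type alone the Sγ1 difference was 12.5. The share of junctions beyond the 90th percentile of control distances was 34.99% ± 2.19 in Sμ (n = 4) against 10.2% ± 2.07 (n = 6, adjusted exact p = 0.0147), 24.8% ± 3.45 in Sγ1 against 11.5% ± 5.96 (0.0147) and 21.3% ± 3.99 in Sε against 10.1% ± 1.07 (n = 4 and 5, 0.0225), and the Sε call ended without DNA-PKcs-null replicate 3 (12.0) or 4 (10.2).

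Of the 3 mutants, Xrcc4-null cells had the largest mean shifts in Sε share, in blunt joins and, in Sγ1 and Sε, in inversion. Sε held 5.47% ± 0.656 of junctions (n = 2) against 43.6% ± 4.89 in controls (n = 6), Sμ 48.1% ± 2.74 and positions outside IgH 14.5% ± 0.0602 against 6.50% ± 1.20. Only 5.39% ± 0.417 of Sγ1 and Sε joins were blunt against 25.3% ± 2.27, with 5.48% in Sγ1 and 5.04% ± 2.30 in Sε, and 26.2% ± 2.10 had long microhomology against 6.86% ± 1.23. Inversional joins made up 33.5% ± 3.26 of them against 7.20% ± 1.19, whereas in Sμ they made up 34.5% ± 2.60, below the 37.1% of DNA-PKcs-null cells. With 2 animals the comparison cannot fall below an exact p of 0.0714, the value of each difference in this paragraph. The adjusted p of each was 0.116, and 0 of 34 measures passed, with 0 at an unadjusted p under 0.05. The 2 libraries come from different runs. The library in run 1, replicate 2, had 5.01% of its junctions in Sε (Wilson 3.91 to 6.39), and the wild-type libraries of that run had 39.3% to 50.7%.

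**Figure D3:**
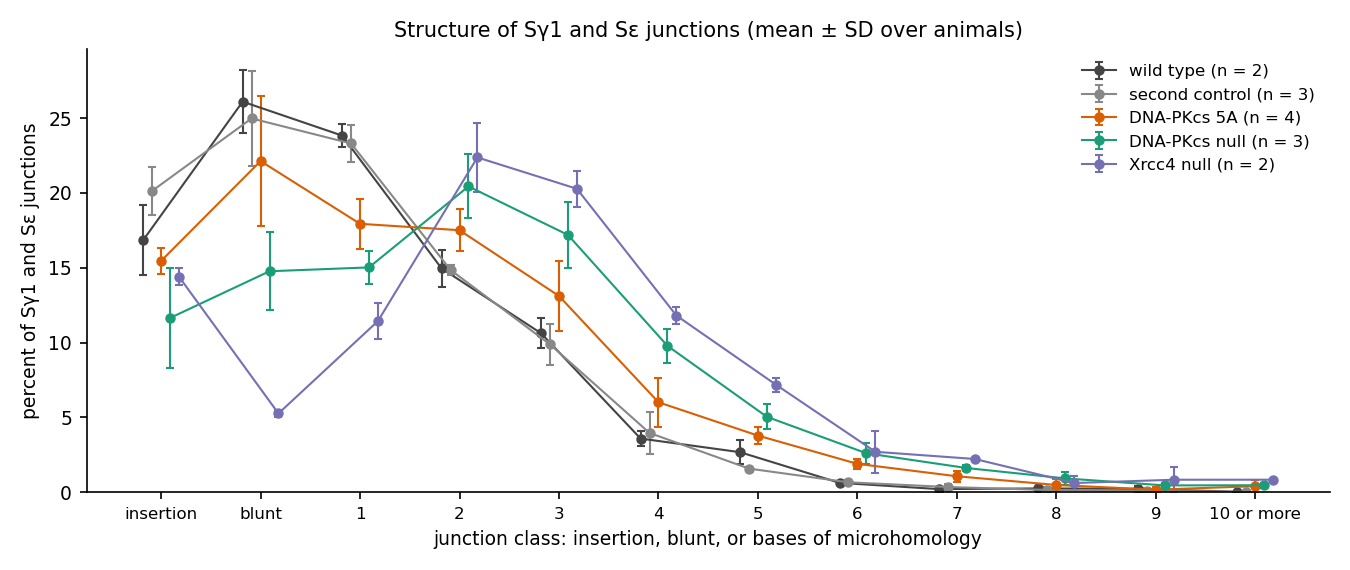
Percent of Sγ1 and Sε junctions (y axis, mean ± SD over animals with join lengths for both regions) by insertion, blunt join or number of shared bases (x axis) for each group. By group mean, blunt joins are the commonest class in wild type (26.1%), the second control group (25.0%) and 5A (22.1%). Joins with 2 shared bases are the commonest by mean in DNA-PKcs-null (20.4%) and Xrcc4-null (22.4%). Not every animal follows its group mean, as 5A animal 1 had 18.1% blunt joins and 18.6% with 1 shared base.

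Among animals with join lengths for both regions, single shared bases fell in mean from 23.8% of Sγ1 and Sε junctions in wild type (n = 2) and 23.3% in the second control group (n = 3) to 17.9% in 5A (n = 4), 15.0% in DNA-PKcs-null (n = 3) and 11.4% in Xrcc4-null cells (n = 2). Joins with 4 shared bases stood at 3.59%, 3.97%, 6.02%, 9.79% and 11.8% in the same order, and joins with 10 or more at 0.0382%, 0.0315%, 0.409%, 0.472% and 0.843%. These lengths were not tested one by one, and they too carry the mix of Sγ1 and Sε joins in each group.

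Set directly against each other, 5A junctions in Sγ1 and Sε kept more blunt joins and less long microhomology than DNA-PKcs-null junctions. Blunt joins were 22.7% ± 4.03 (n = 5) against 14.0% ± 2.58 (n = 4) in Sγ1 and Sε, and long microhomology 14.6% ± 2.80 against 20.9% ± 0.208. In Sε alone long microhomology was 8.73% ± 1.62 against 15.4% ± 0.999, and in Sγ1 alone 19.3% ± 1.95 against 23.4% ± 1.18. The Sγ1 share was 21.5% ± 2.55 against 29.2% ± 3.55. Each of these had no overlap between animals and an exact p of 0.0159, the smallest possible, but an adjusted p of 0.0540, and 0 of 34 measures passed with 16 at an unadjusted p under 0.05. In Sμ, long microhomology was not shown to differ (-1.15 percentage points, adjusted exact p = 0.580). By region, blunt joins differed by 4.40 percentage points in Sμ, 5.54 in Sγ1 and 10.3 in Sε (adjusted exact p = 0.101 for each). The Sε share (20.4% ± 12.6 against 12.8% ± 4.74, adjusted exact p = 0.475) and the inversional share of Sγ1 and Sε (7.71% ± 4.15 against 11.2% ± 0.873, 0.308) overlapped, while the inversional share of Sε alone did not (2.15% ± 1.43 against 6.89% ± 2.73, n = 5 and 4, exact p = 0.0159, adjusted 0.0317 over both regions). With Sε alone in place of the pooled inversional share among the 34 measures, its adjusted exact p was 0.0491. Run 2 holds 1 library of each genotype, whose Sε shares differed by 24.6, long microhomology by -10.04 and inversional joins by -7.09 percentage points. In run 1, with 4 animals against 1, the Sε share differed by -2.83, the opposite direction.

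Compared with Xrcc4-null cells, 5A cells had more Sε junctions (20.4% against 5.47%), more blunt joins (22.7% against 5.39%), less long microhomology (14.6% against 26.2%), fewer inversional joins (7.71% against 33.5%) and fewer junctions outside IgH (8.04% against 14.5%). All of these had an exact p of 0.0952, the smallest that 5 animals against 2 allow, and an adjusted p of 0.190, so 0 of 34 measures passed, with 0 at an unadjusted p under 0.05.

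**Figure D4:**
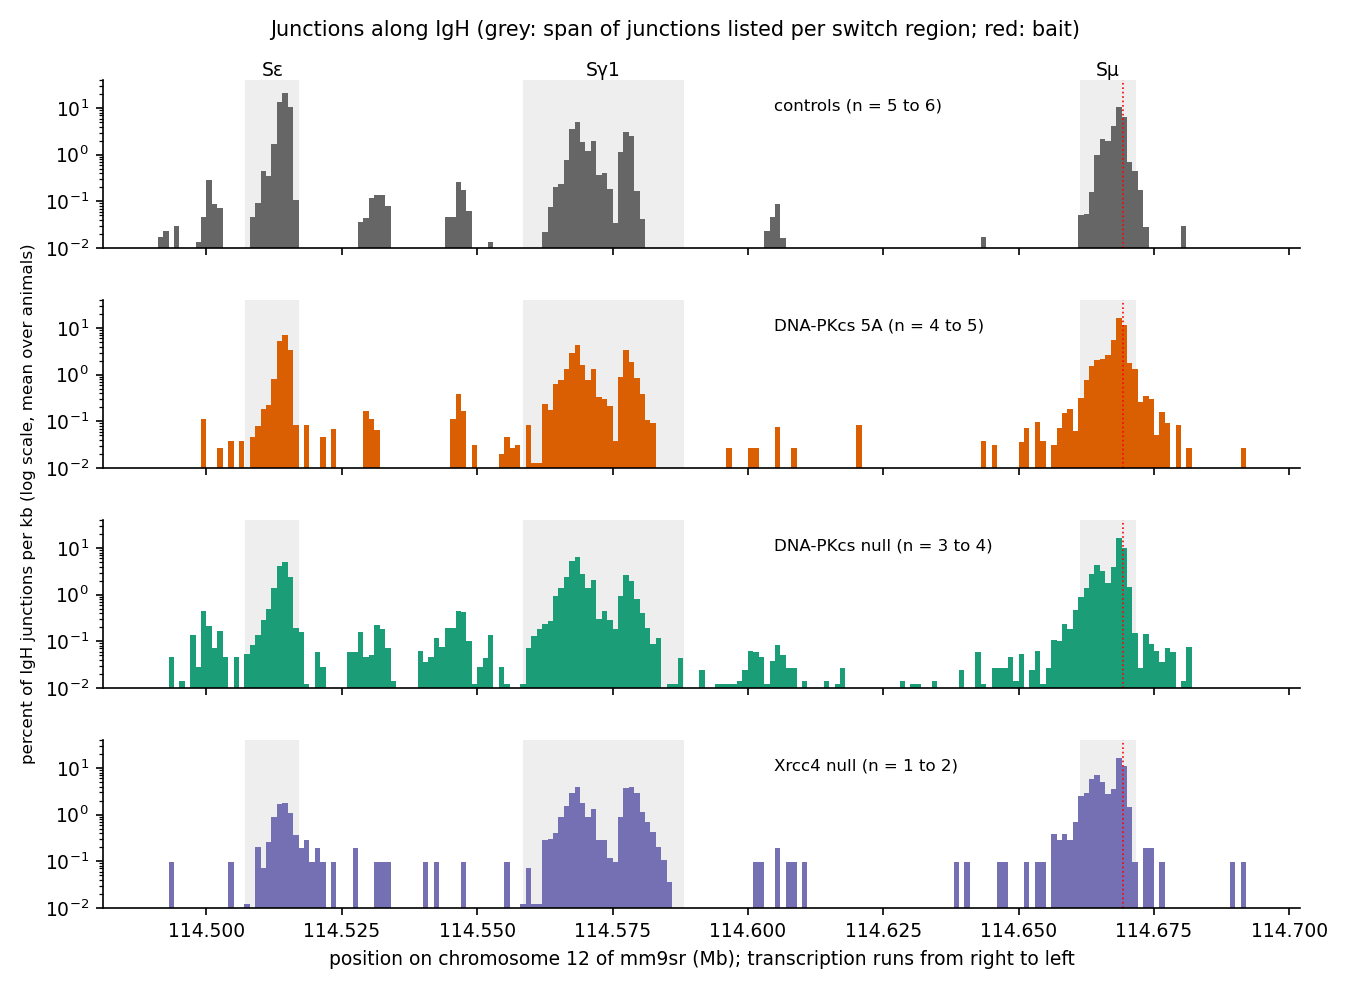
Percent of IgH junctions per kilobase (y axis, log scale, mean over animals whose list of a region was used) along IgH in mm9sr (x axis, Mb on chromosome 12), with the junction span of each switch region in grey and the bait as a red dotted line. The Sε peak is lower in all 3 mutant panels than in controls, and junctions just downstream of Sμ, 0.0365% of IgH junctions in controls, reach 0.891% in 5A.

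Outside IgH, 1405 junctions were listed from 15 libraries, and the 10 windows of mm9 with junctions in most libraries held 266 of them (18.9%). These windows were on chromosome 12 at 114 Mb (14 libraries, 45 junctions), the window that holds the bait, chromosome 7 at 132 Mb (13 libraries, 55 junctions), chromosome 14 at 67 Mb (13 libraries, 22 junctions), chromosome 12 at 70 Mb (12 libraries, 37 junctions) and chromosome 6 at 70 Mb (11 libraries, 30 junctions). The others were chromosome 16 at 19 Mb (11 libraries, 12 junctions), chromosome 6 at 129 Mb (9 libraries, 21 junctions), and chromosome 12 at 81 Mb, 88 Mb and 113 Mb, each in 8 libraries. In the chromosome 7 window 35 junctions lay in introns of Il4ra (132695785 to 132722986), the receptor subunit for the interleukin 4 in the culture. Clec2d on chromosome 6 held 18 (15 intronic), 1110034A24Rik on chromosome 12 held 17, and Zfp36l1 and Tmed8 on chromosome 12 held 16 and 12. The 22 junctions on chromosome 14, from 13 libraries and every group, all lay within 67781261 to 67781264, in no annotated gene. Whether they come from independent breaks was not tested, and they are part of the 266. The counts per library are too low to compare these windows between groups.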

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

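The tests of the 3 patterns below, of the gap between Sε and Sγ1 and of IgH junctions outside the switch regions were chosen only after the results were seen.

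Single animals far from the rest of their group were looked for in 97 combinations of group and measure. Chance marks about 1 in 20 of these, or 4.85, and 9 were found. The other IgH share of DNA-PKcs-null animal 2 was 11.4%, against 4.96% to 6.01% in the other 3. Insertions in Sγ1 and Sε of 5A animal 4 were 7.50% (6 of 80 junctions), against 14.4% to 16.7%. Blunt joins in Sγ1 of 5A animal 5 were 10.1%, against 17.1% to 18.6%. Mean microhomology in Sγ1 of second-control animal 4 was 1.74 bases, against 1.43 to 1.48. Microhomology in Sε of DNA-PKcs-null animal 4 was 65.8%, against 69.4% to 69.9%. Insertions in Sε of DNA-PKcs-null animal 2 were 5.69%, against 12.2% to 12.4%. The median distance in Sγ1 was 16.8 kb in second-control animal 1, against 19.2 to 19.3 kb. It was 19.4 kb in 5A animal 3, against 18.8 kb in the other 3 animals with a value. The median bait length of 5A animal 4 was 63.5 bases, against 59 to 60.

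Junction structure in 5A changed differently in Sε and Sγ1. The gap Sε minus Sγ1 within each animal exceeded that of controls by 12.7 percentage points for blunt joins (14.6 ± 8.89, n = 5, against 1.81 ± 2.29, n = 6, adjusted exact permutation p = 0.0476 over 15 tests). Carry-over of reads from control libraries is argued against in 4 of the 5A libraries, where 8.47% of the listed Sε junctions (35 of 413) were identical to a control junction, and stays open in replicate 2, whose lists of Sε junctions leave out blunt joins. A gap set by 1 library is argued against by the unadjusted exact permutation p (highest without 1 of the 5A libraries 0.0381), but the adjusted call ended without replicate 2 (difference 13.3), 3 (13.3), 4 (9.72) or 5 (11.7), each at 0.0952. A shortage of microhomology between Sμ and Sε stays open, since the null mutants differ in the gap for long microhomology. That gap was 0.343 and 2.04 percentage points in the 2 Xrcc4-null animals, and the lower value rests on 60 Sε junctions. In the 4 DNA-PKcs-null animals it ran from -10.8 to -6.08, the direction that a shortage would give. An effect of the 5A protein was not tested and stays open.

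The other gaps against controls in 5A were -8.55 percentage points for long microhomology and -10.5 for any microhomology (adjusted exact permutation p = 0.0325 for both). In DNA-PKcs-null animals they were 7.98 for blunt joins, -5.93 for long microhomology (adjusted exact p = 0.0357 for both) and -5.49 for any microhomology (0.0476). The gap was not shown to differ between 5A and DNA-PKcs-null (exact p = 0.333 for blunt joins, 0.0794 for long and 0.0952 for any microhomology).

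The 5A library of replicate 2 had an Sε share of 39.3%, inside the control range. A control library under a 5A label is argued against by its Sγ1 joins, of which 17.4% had long microhomology (Wilson 14.0 to 21.5), above the highest control library at 10.9%. An effect of its sequencing run cannot be told apart from a difference between animals. The DNA-PKcs-null library of that run had an Sε share of 14.6%, inside the range of the other 3 of its group, and 1 library does not decide.

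IgH junctions upstream of Sμ, which no comparison of switch regions counts, were more frequent in 5A than in controls, 3.65% ± 2.30 (n = 5) against 0.616% ± 0.283 (n = 6), with an exact permutation p of 0.00433, adjusted 0.0289 over 20 tests. Without 5A replicate 4, the shallowest library, the difference dropped from 3.04 to 2.10 percentage points. The 5A mean was then 2.71% (exact permutation p = 0.00952, the smallest possible there). Repeated copies of a few junctions are argued against by the 95.2% of 104 junctions at distinct positions. The sequencing run is argued against by run 1 alone (4.28% against 0.553%, n = 4 and 5, exact p = 0.0159). Fewer Sγ1 and Sε joins could also raise the upstream share. DNA-PKcs-null animals kept a similar share of these joins but had 0.788% ± 0.101 upstream (n = 3), with no overlap with 5A. That difference missed the threshold (exact p = 0.0357 against 5A, adjusted 0.0893). Within 5A, the mean was 2.71% without replicate 4, which had the lowest Sε share, and 4.28% without replicate 2, which had the highest. This explanation is therefore not excluded. A biological cause tied to the 5A protein is a hypothesis from the same data, and other differences between these mice stay open.

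Junctions between Sμ and Sγ1 made up 1.17% ± 0.236 of IgH junctions in 5A (n = 5), 2.56% ± 0.444 in DNA-PKcs-null (n = 3) and 3.71% in the 1 Xrcc4-null library with a value, against 0.217% ± 0.0949 in controls (n = 6). Those in the first 20 kb past Sμ made up 0.891% ± 0.250, 1.90% ± 0.563 and 2.83%, against 0.0365% ± 0.0460. For both, the exact permutation p against controls was the smallest the number of animals allows, 0.00433 in 5A, 0.0238 in DNA-PKcs-null and 0.286 in Xrcc4-null (adjusted 0.0289, 0.0893 and 0.408), so these p-values do not rank the groups.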

How the results depend on the processing

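Averaging the 2 wild-type libraries of 1 animal was chosen after seeing the data, so each library as a replicate, the planned form, was added as an alternative then, as was leaving out each library for the share of distant junctions. The other alternatives were planned. The tally covers 87 differences, selected after the values were seen. Of their 1585 alternative values, 1329 kept their direction and, where a test was run, their side of the threshold. Pooled junctions and the fit of 1 library against 1 in run 2 were not tested. There a difference with its direction held was counted as kept if it changed by less than the mean SD of the 2 groups, and as moved otherwise. The direction held but the call was lost in 188, while 18 gained a call, 13 moved and 37 turned. The comparisons of Xrcc4-null with controls and of 5A with Xrcc4-null gave 250 and 142 of the 1329. No call was possible in these 2 comparisons, so their side of the threshold was fixed beforehand. Over all 125 differences 80 of 2122 alternatives turned, and among the 38 not selected 43 of 537. In 5A against controls, calls for the Sε share and long microhomology in Sγ1 and Sε were lost within run 1 (-27.2 and 8.55 percentage points), against wild type alone (-26.0 and 6.99) and against the second control group alone (-21.8 and 8.17). In each of these 3 settings all 12 calls among the 25 differences described were lost. Each of these has fewer animals and a higher smallest p. The call for long microhomology was lost in Sε alone (2.59) and with each junction counted once (7.71, n = 3 and 5). Blunt joins were called over all IgH junctions (-8.001) and in Sγ1 alone (-7.62) and turned positive in Sε alone (5.12). Depth limits Sε structure most in 5A replicate 4, with 20 Sε junctions.

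Other 5A values turned sign, and the cause was not tested. The Sγ1 share became 0.0123 (log odds), 0.402 (run 1), 10.3 (percent of junctions outside Sμ), 0.299 (percent of IgH junctions), 4.84 (wild type alone) and 0.316 (each library as a replicate). Inversional joins in Sγ1 and Sε became -0.822 (junctions pooled), -0.00203 (log odds) and -2.95 (Sε alone). Median distance became -0.00382 kb in Sε (pooled), and in Sμ -0.00647 kb (run 1), -0.0430 kb (both orientations) and -0.0123 kb (each library as a replicate). Microhomology of 6 or more bases in Sε was -0.0486, and bait length against wild type alone 0.550 bases. Leaving out 1 library at a time gave -27.9 to -20.0 for Sε, -0.820 to 1.37 for inversional joins, -1.49 to 1.06 for Sγ1 and -0.0318 to 0.0810 kb for median distance in Sμ.

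Pairing of animals by replicate number was not detected, as 5 of 16 pairs correlated over 0.1 across 27 measures (-0.361 to 0.392). The measures depend on each other and the check had no reference for paired animals, so it cannot exclude pairing. The replicate block compares with wild type only, as the second control group has no single series of numbers. Its pairs of numbers 2 and 3 share 1 wild-type animal, so they are not independent. The exact p of the block cannot fall below 0.25 with 3 pairs, so no call was possible there. For 5A it gave -18.9 (Sε), 5.37 (long microhomology), 4.28 (Sγ1 share), -0.696 (blunt joins in Sε), -0.0652 kb and, with 2 pairs, -0.0760 kb (median distance in Sμ and Sε), 0.0317 (bait substitutions) and -0.730 (chromosome 12 share). For DNA-PKcs-null the replicate block gave -34.0 (Sε), -12.8 (blunt), 13.3 (long microhomology) and 4.15 (inversional).

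In DNA-PKcs-null against controls, all 19 calls among 25 differences were lost within run 1, which holds 1 such library (-24.4 for Sε, -10.3 for blunt, 13.6 for long microhomology and 4.40 for inversional joins, with bait length at -0.700 bases), against the 2 wild-type animals (-33.5, -12.1, 13.2 and 4.53), and the inversional call in Sγ1 (1.24) or Sε (1.79) alone. Against the second control group alone 15 calls held and 4 were lost, for Sγ1 share (5.18), blunt joins in Sε (-4.55), mean microhomology (1.00) and median distance in Sε (0.239 kb). In 5A against DNA-PKcs-null, Sε was 16.7 with junctions pooled, -2.83 in run 1 and 24.6 in run 2, long microhomology -8.21 pooled and -10.04 in run 2, and inversional joins -7.09 in run 2. In Sε alone inversional joins were called, at -4.74. Against Xrcc4-null, pooled 5A junctions gave 22.0 (Sε) and -14.5 (long microhomology).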

Other observations

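The values in this part were chosen only after the results were seen, and no test was made between groups. Of the 104 listed 5A junctions upstream of Sμ, 56 lay within 5 kb of it, 64 were inversional, 68.3% had microhomology and 12.5% were blunt. Of these, 102 could be placed in mm9, on chromosome 12 between 114667171 and 114738694. In the first 20 kb past Sμ, 34 listed 5A junctions had microhomology in 85.3% and were blunt in 5.88%, and 10 lay in Gm11029. The 99 DNA-PKcs-null junctions there had microhomology in 72.7% and were blunt in 12.1%, and 21 lay in Gm11029, a gene named after its values were seen.

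The 2 libraries of 1 wild-type animal shared 30.5 identical junctions per 1e6 pairs of junctions. Libraries of different animals had a median of 9.66 within a run (highest 107) and 10.3 between runs (highest 114).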
